A study of Mus musculus with 11 samples.

How the data were processed

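The samples were 11 libraries of sorted mouse thymic fibroblasts, 4 untreated, 3 taken 18 h and 4 taken 4 d after dexamethasone. Per the labels' protocols, RNA was made into libraries with MARS-seq, which reads the 3' ends of polyadenylated transcripts. The titles of the later group read 3 d where its descriptions and treatment text read 4 d, and 4 d is used here. The labels list EpCAM as positive in the sort, and Epcam levels are given with the results. The untreated libraries are numbered 1 to 4 in the titles and 1, 3, 4 and 5 in the descriptions, and the title numbers are used.

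Per the submitters' processing notes, the tools were bcl2fastq, cutadapt, STAR 2.5.2b, HTSeq and DESeq2, with the build mm10. Whether molecular identifiers were collapsed, the strand setting and the annotation are not given in the sources used here, so reads of overlapping genes on opposite strands may not be separable. The authors deposited whole-number counts per gene symbol and library, per the file headers, and these were the input of every test. Each listed gene had at least 6 counts in at least 1 library. The authors also deposited a normalized signal, which equals the counts times 1 constant per library, and it was not used in tests. The deposited table further held the authors' log2 fold changes and adjusted p-values for the 3 comparisons, of which the number of genes below an adjusted p of 0.05 is quoted, with the number of these also called here in the same direction. The table held 12430 genes, with no column left unmatched to a sample. Counting noise was largest in 18 h replicate 2 and 4 d replicate 4, at 924731 and 916281 counts, where a count of 0 allows up to 3.65 and 3.74 CPM, against 1.00 CPM in the deepest library. These limits cover counting error only. The 15 pairs of replicates all differed by more than sampling noise, with a chi-square per degree of freedom of at least 4.79, so none was treated as a repeat of another.

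Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3) with a minimum count of 10, which left 10067, and libraries were scaled by TMM. All 11 libraries entered 1 quasi-likelihood fit with robust dispersion estimates, with group as the only term, and each of the 3 comparisons was a contrast of it. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The SE of a log2 difference was its size divided by the square root of the quasi-likelihood F. Of 35 gene lists, fixed before the data were examined, 34 had at least 3 tested members. They covered glucocorticoid, type 2, thymus growth factor, retinoic acid, fibroblast, matrix, interferon, inflammatory, stress, metabolic and clock genes and markers of other cell types. The remaining list, mitochondrially encoded genes, had 0 members in the table. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over 102 tests, and again with an estimated correlation. With the preset value 11 lists were called upward and 1 downward at 18 h, 11 and 0 at 4 d, and 6 and 8 between 18 h and 4 d. With the estimated correlation camera called 0, the lowest adjusted p being 0.156, and 4, 1 and 3 lists had an unadjusted p below 0.05. The directional fry test, which asks only whether the genes of a list move one way, called 9, 1 and 6 lists, and its mixed form 28, 20 and 20. The median, the mean and the camera direction differed in sign for 3 lists at 18 h (retinoic acid, remodelling and cholesterol synthesis), 7 at 4 d (TGF-beta, interferon, complement, circadian clock, cholesterol synthesis, hypoxia and thymic epithelium) and 5 between the times (cholesterol synthesis, adipogenesis, endoplasmic reticulum stress, the granulocyte and innate lymphoid markers and the mesothelium, Schwann and erythroid markers). List members were also counted after adjustment over the list alone. Marker sums per library were compared with exact two-sided permutation tests in scipy 1.17.1.

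The rule for named genes was fixed before the data were examined. It took, per comparison, the 8 largest and the 8 smallest log2 differences among genes that passed, with a mean count of at least 10, no overlap between the groups and an ordinary symbol, up to 4 members per list with the smallest adjusted p, and 23 genes named in advance, such as Il33, Il4ra, Bmp4 and Igf1. From these the text names preferably genes whose call held when each library in turn was left out. That was so for 59 of 82 named calls at 18 h, 24 of 53 at 4 d and 36 of 59 between the times, among the 159 genes looked up. The result of 1 gene that the rule named is not reported here, although it stayed in the fits. Coordinates are those of GENCODE on GRCm38, which has the sequence of mm10, matched by symbol for 158 of the 159, and each is the span of the gene, protein-coding for 157 and a long intergenic noncoding RNA for 1.

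On simulated counts with known changes, the fit recovered 92.9% of 4-fold and 21.0% of 2-fold changes in the design of the 18 h comparison (9974 genes), 91.9% and 28.3% at 4 d (9969 genes) and 89.0% and 22.0% between the times (9972 genes). False calls were 6 of 119, 10 of 129 and 6 of 117 calls. The simulated genes varied independently, with a dispersion set by expression level alone, so the rates for the real libraries may differ. The alternatives were other scalings, DESeq2 1.42.0 and limma-voom, no filter and a filter of 20 counts, the 2 groups alone, a 2-fold limit, replicate numbers as a block, ribosomal protein genes left out, and each library left out in turn. Every fit filtered the genes anew, so the number of list members tested could change with the library left out. Chosen after seeing the data were a fit without the 2 shallow libraries, a covariate with the mean log2 CPM of endothelial, macrophage and pericyte markers, and one with 4 mesothelial markers. The first covariate, called the marker covariate, was 4.12 to 5.64 in the 18 h libraries and 2.82 to 3.95 in the others. It thus nearly follows the 18 h group. Calls of the 18 h comparisons lost with it may reflect lost precision. For some genes the estimate itself shrank or changed sign. Neither shows other cells as the source. Ranges and highest values of a list's adjusted p over the alternatives include the fits chosen after seeing the data. They leave out the replicate blocks and the estimated correlation. No vehicle-injected group is among the samples used here, so injection and dexamethasone are not separated.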

Results

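Thymic fibroblasts, the stromal cells that form the capsule and septa of the organ in which T cells develop, were profiled by MARS-seq, a method that counts the 3' ends of polyadenylated transcripts. Young male wild-type mice received dexamethasone, a synthetic glucocorticoid that causes the thymus to shrink, at 200 ug per 10 g body weight, and fibroblasts were sorted 18 h or 4 d later. Age-matched mice that received no injection were the reference. The series concerns how the thymus recovers and the part that fibroblasts and type 2 immune signals play in it. There were 4 untreated libraries, 3 at 18 h and 4 at 4 d. Total counts were 1823732, 1687549, 2432295 and 2398275 in untreated replicates 1 to 4, 1915579, 924731 and 2290284 at 18 h, and 2647878, 2729207, 3357113 and 916281 at 4 d. The labels call the samples replicates without saying that each came from a separate animal, so the p-values measure only the spread between these samples, which may be technical. Log2 differences are given with their standard errors (SE) and adjusted p from edgeR's quasi-likelihood test, and levels as CPM, counts scaled to a common library size, with the SD.

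The first comparison asked what fibroblasts expressed 18 h after dexamethasone. Inflammatory cytokine and chemokine genes rose as a list. Its member Saa3, an acute-phase serum amyloid (protein-coding, chromosome 7, 46711998 to 46715700, GRCm38), rose from 114 ± 17.4 CPM (SD, n = 4) to 16553 ± 6746 CPM (SD, n = 3), a log2 difference of 7.19 ± 0.35 (adjusted p = 5.5e-08). The granulocyte growth factor Csf3, also in the list, rose by 6.56 ± 0.60 on the log2 scale. Outside it, Lcn2, which encodes an iron-sequestering protein (chromosome 2, 32384633 to 32388252), rose by 6.99 ± 0.45, the haptoglobin gene Hp by 5.75 ± 0.63 and Lrg1 by 7.80 ± 0.77, the last from only 5 counts in the untreated group. Saa1 rose by 6.07 ± 0.68, an uncertain value because counting can split reads between it and its near copy Saa2. Of 29 tested inflammatory cytokines and chemokines, 18 rose and 0 fell (24 higher adjusted over the list alone), among them the chemokines Ccl3 at 5.71 ± 0.81 and Cxcl2 at 2.51 ± 0.36. The list stood above the other genes (camera adjusted p = 8.3e-15, and adjusted p = 0.512 with an estimated correlation). Without 18 h replicate 3, 11 of its members rose.

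**Figure D1:**
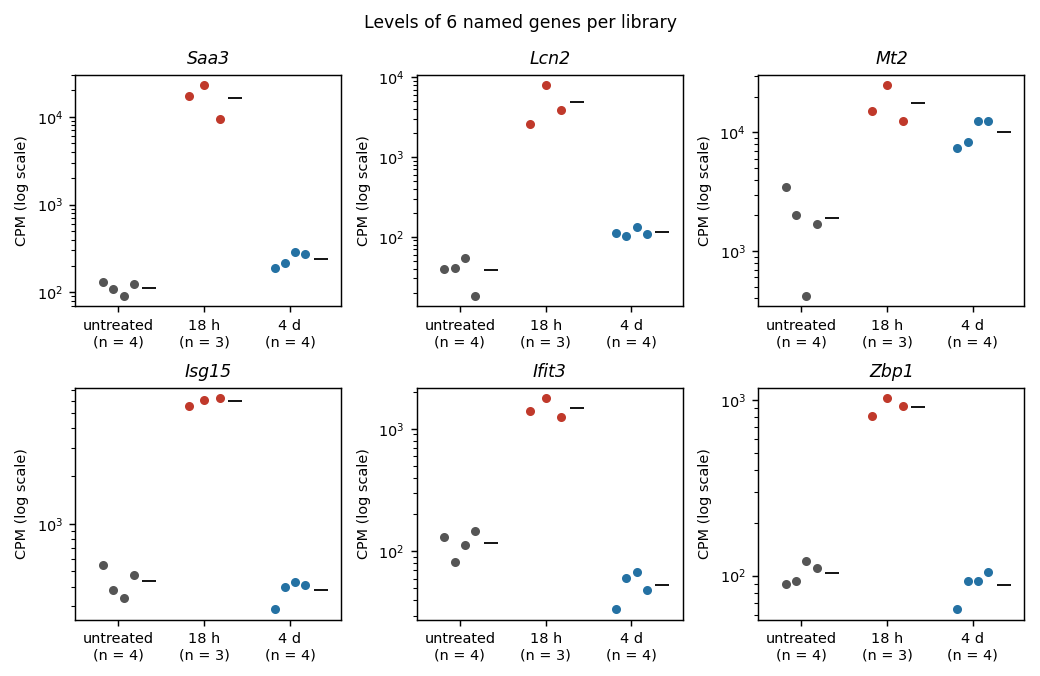
CPM on a log axis for 6 genes, with a point per library in the untreated (n = 4), 18 h (n = 3) and 4 d (n = 4) groups and a short line at each group mean. Saa3 averaged 114 CPM in untreated libraries, 16553 CPM at 18 h and 241 CPM at 4 d, and Isg15 averaged 436, 5939 and 382 CPM.

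Interferon-response genes rose together at 18 h. Of the 31 tested, 28 were higher and 1 lower (30 higher and 1 lower adjusted over the list alone), with a median log2 difference of 2.21. Isg15, a ubiquitin-like protein induced by interferon (chromosome 4, 156199424 to 156200818), went from 436 ± 93.5 CPM (SD, n = 4) to 5939 ± 344 CPM (SD, n = 3), a difference of 3.77 ± 0.25 (adjusted p = 6.6e-07). The nucleic acid sensor Zbp1 rose by 3.14 ± 0.23, Usp18, which removes Isg15 from proteins, by 2.98 ± 0.23, and Ifit3 by 3.64 ± 0.28, the last uncertain because reads may be shared with Ifit3b. The lower member, named after its value was seen, was Ifi27 at -1.18 ± 0.21. Camera placed the list above the other genes (adjusted p = 3.8e-23, and adjusted p = 0.156 with an estimated correlation). Nlrc5, the activator of MHC class I genes, rose by 3.58 ± 0.35, in an antigen presentation list of 12 genes with a median of 0.90 (camera adjusted p = 0.00475, and adjusted p = 0.584 with an estimated correlation). With the mean of endothelial, macrophage and pericyte markers as a covariate, that list gave an adjusted p of 0.947, the highest of 21 alternatives that began at 2.5e-04.

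Endothelial and macrophage markers were also higher at 18 h. Endothelial markers summed to 3307 ± 1242 CPM (SD, n = 3) against 722 ± 212 CPM (SD, n = 4) in untreated libraries, macrophage and monocyte markers to 605 ± 203 against 225 ± 59.2 CPM, and pericyte and smooth muscle markers to 762 ± 412 against 271 ± 112 CPM. In each of these sums every 18 h library lay above every untreated library, and the exact two-sided permutation test gave p = 0.0571, the smallest p that 3 against 4 libraries allow (adjusted p = 0.140 over 27 tests). Single endothelial genes passed the gene test, with Pecam1 at 4.73 ± 0.75, Flt1, a receptor for vascular growth factors, at 4.42 ± 0.70 and the junction gene Cldn5 at 6.55 ± 1.14. Of 10 tested endothelial markers 7 rose (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00284, and adjusted p = 0.512 with an estimated correlation), and without 18 h replicate 2, when 17 passed the filter, 14 did, 7 of them among the same 10. Of 15 macrophage markers 7 rose (9 adjusted over the list alone; camera adjusted p = 3.3e-04, and adjusted p = 0.512 with an estimated correlation), including Cybb, a subunit of the phagocyte oxidase, at 4.08 ± 0.77 and Cd68 at 1.16 ± 0.23, with 3 higher without 18 h replicate 1 and 4 without 18 h replicate 3. Of 13 pericyte and smooth muscle markers 4 rose and 1, Abcc9, named after its value was seen, fell (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.139), with Mcam at 3.54 ± 0.65 and Tagln at 2.90 ± 0.49, and 2 rose without 18 h replicate 1. The count of lower ones was 0 without untreated replicates 2, 3 or 4 or 18 h replicates 2 or 3. The size for Mcam is uncertain, since it was at 5.68 CPM in untreated replicate 4 and 1.04 to 1.43 CPM in the other untreated libraries. The pericyte list was called without untreated replicate 4 (0.0354), 18 h replicate 2 (0.0388) or the 2 shallow libraries (0.0378) and with no filter (0.0294). With a filter of 20 counts the endothelial and macrophage lists lost their calls (0.222 and 0.086). Over the alternatives their adjusted p ran from 3.6e-13 to 0.636 and from 1.5e-05 to 0.665. The upper ends came with the covariate made of these same markers, which removes their change by construction.

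Sums of 2 further marker lists were separated from untreated in the same way. Those of eosinophils, neutrophils, mast cells and innate lymphoid cells were at 76.1 ± 57.8 CPM (SD, n = 3) against 15.9 ± 6.03 CPM (SD, n = 4), and those of dendritic and B cells at 4112 ± 278 against 689 ± 67.7 CPM, each with an exact two-sided permutation p = 0.0571 (adjusted p = 0.140). The latter rested largely on 1 gene. Bst2, which tethers budding viruses and is in both the interferon list and the dendritic and B cell list, rose by 2.58 ± 0.23 and was at 4039 ± 269 CPM at 18 h (SD, n = 3), close to the whole sum of the latter list. That list of 4 tested genes gave a camera adjusted p of 0.00420 (adjusted p = 0.512 with an estimated correlation). At the preset correlation and without a replicate block its adjusted p ranged from 6.5e-05 to 0.111, where the marker covariate ended the call. Several other genes, such as Tagln and Fabp4, are likewise in more than 1 list, so lists are not independent. Medians of the remaining markers were 1.18 for thymocytes (camera adjusted p = 0.101), 0.63 for tuft cells (0.123, and fry adjusted p = 0.0403 upward), 1.08 for eosinophils, neutrophils, mast cells and innate lymphoid cells (0.536), 0.12 for thymic epithelium (0.880) and -0.48 for mesothelium, Schwann and erythroid cells (0.434). The thymocyte list was called without untreated replicate 2 (0.0284), 18 h replicate 2 (0.0495) or the 2 shallow libraries (0.0270), with limma-voom (0.0415) and with only the 2 groups compared (0.0498). The tuft list was called without 18 h replicate 2 (0.0357) or the 2 shallow libraries (0.0341), and the granulocyte and innate lymphoid list with no filter (0.0108). Epcam, which the labels place among the positive sort markers, was at 3.14 ± 4.82 CPM in untreated libraries (SD, n = 4) and 2.96 ± 1.79 CPM at 18 h (SD, n = 3).

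**Figure D2:**
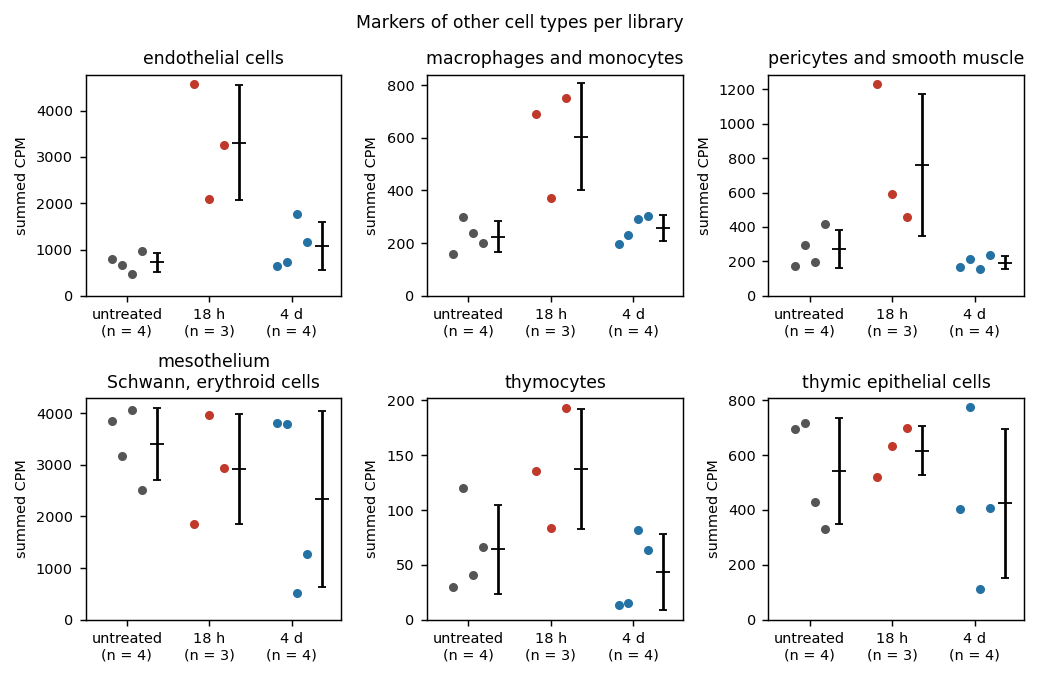
Summed CPM of 6 marker lists, with a point per library in the untreated (n = 4), 18 h (n = 3) and 4 d (n = 4) groups, and a line with bars for the mean and SD of each group. Endothelial sums ran from 2090 to 4572 CPM at 18 h and from 465 to 971 CPM in untreated libraries.

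Genes known to respond to glucocorticoids went both ways at 18 h. The metallothionein genes Mt2 and Mt1, which bind metal ions, rose by 3.21 ± 0.51 and 2.80 ± 0.48, uncertain values since reads may be shared between these near copies, and Ddit4, an inhibitor of mTOR signalling, rose by 1.51 ± 0.27. Nr3c1, which encodes the glucocorticoid receptor, fell by 1.61 ± 0.27 on the log2 scale (adjusted p = 0.00195), while Fkbp5 and Tsc22d3 stood at 0.43 ± 0.49 and -0.44 ± 0.38, with neither past the threshold. Of 23 tested, 6 rose and 4 fell (9 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.131, and fry adjusted p = 0.0296 upward). The lower count was 1 without untreated replicate 2 or 18 h replicate 1 and 2 without untreated replicates 3 or 4 or 18 h replicate 2. Among 13 circadian clock genes 4 fell and 0 rose (4 lower adjusted over the list alone; fry adjusted p = 0.0296 downward), led by the clock output factors Dbp at -3.75 ± 0.78 and Hlf at -2.74 ± 0.56. The clock list gave a camera adjusted p of 0.0654, which became 0.0236 without untreated replicate 3, 0.0249 without 18 h replicate 2, 0.0299 without the 2 shallow libraries and 0.0386 with no filter. Without 18 h replicate 1, 2 clock genes fell. The sample information used here holds no time of day of collection, so for clock genes it is not separated from the time after dexamethasone. With the marker covariate the calls of Dbp and Hlf ended at -2.92 and -1.26.

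Matrix genes went both ways at 18 h. The basement membrane collagens Col4a1 and Col4a2 rose by 2.23 ± 0.36 and 1.32 ± 0.27, while the elastic fibre genes Eln, Mfap4 and Mfap2 stood at -1.28 ± 0.24, -1.84 ± 0.31 and -1.78 ± 0.31. Has2, a hyaluronan synthase, rose by 2.82 ± 0.45, the metalloprotease inhibitor Timp1 by 3.97 ± 0.35 and the protease gene Mmp3 by 2.90 ± 0.54. Of 18 collagens 2 rose and 6 fell (2 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.0163 downward, and adjusted p = 0.584 with an estimated correlation). The count of lower collagens was 0 without untreated replicates 2 or 4 or 18 h replicate 2, 1 without 18 h replicate 1, and 3 without 4 d replicates 1 or 4. Of 27 matrix glycoproteins 2 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.359), with 1 higher without 18 h replicate 3, and the 28 remodelling genes had a median of -0.04, a mean of 0.08 and a camera adjusted p of 0.837. The marker covariate ended the calls of Mmp3, at 0.16, Col4a2, at 1.22, and Eln, at -1.27.

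Factors with known roles in thymus growth included more that fell than rose at 18 h. Bmp4, a growth factor for thymic epithelium (chromosome 14, 46383520 to 46390669), fell from 72.2 ± 17.7 CPM (SD, n = 4) to 20.5 ± 8.87 CPM (SD, n = 3), a log2 difference of -1.88 ± 0.30 (adjusted p = 0.0015). Wnt5a, Igf2 and Igf1 stood at -2.05 ± 0.41, -2.12 ± 0.52 and -1.68 ± 0.43, and the chemokine Cxcl12 rose by 1.92 ± 0.47. In all, 3 of 20 such factors rose and 5 fell (3 higher and 7 lower adjusted over the list alone; median -0.67; camera adjusted p = 0.213). The directional fry test called the list downward (adjusted p = 0.0498). Fgf10, which did not pass, had 3 counts in the 18 h libraries together and 51 in the untreated ones. The Igf1 call was lost without untreated replicates 2 or 3 or 18 h replicates 1 or 2 (adjusted p from 0.0550 to 0.0831) and the Cxcl12 call without untreated replicate 3 or 18 h replicates 1 or 3 (0.0514 to 0.0739), and both Igf1 and Igf2 lost theirs without the 2 shallow libraries, at -1.49 and -1.89. The higher count was 0 without untreated replicate 3 or 18 h replicate 3 and 1 without untreated replicate 4 or 18 h replicate 1, and the lower count 3 without untreated replicate 3 or 18 h replicates 1 or 2. Cxcl12 stood at 0.23 with the marker covariate.

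Type 2 immune genes included 3 that rose at 18 h. Il4ra, the receptor chain shared by IL-4 and IL-13 (chromosome 7, 125552120 to 125579474), went from 6.44 ± 3.06 CPM (SD, n = 4) to 22.8 ± 1.49 CPM (SD, n = 3), a log2 difference of 1.83 ± 0.44 (adjusted p = 0.0159). The chemokine Ccl8 rose by 3.78 ± 0.79 and the cytokine signalling inhibitor Socs1 by 1.40 ± 0.30. Il33, an alarmin of type 2 responses, stood at -0.06 ± 0.41 and did not pass. Of 12 tested members 3 rose and 0 fell (4 higher adjusted over the list alone; camera adjusted p = 0.0139, and adjusted p = 0.512 with an estimated correlation), and 5 of the 14 then tested rose without 18 h replicate 2. The list call was lost without 18 h replicate 3 (0.0988), with a filter of 20 counts (0.208) and with the marker covariate (0.947), the range over the alternatives being 2.3e-04 to 0.947. That covariate also ended the calls of Il4ra, at 1.20, Ccl8, at 2.42, and Socs1, at 0.79. Because it was higher in every 18 h library than in any other, these lost calls do not show that other cells were the source.

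**Figure D3:**
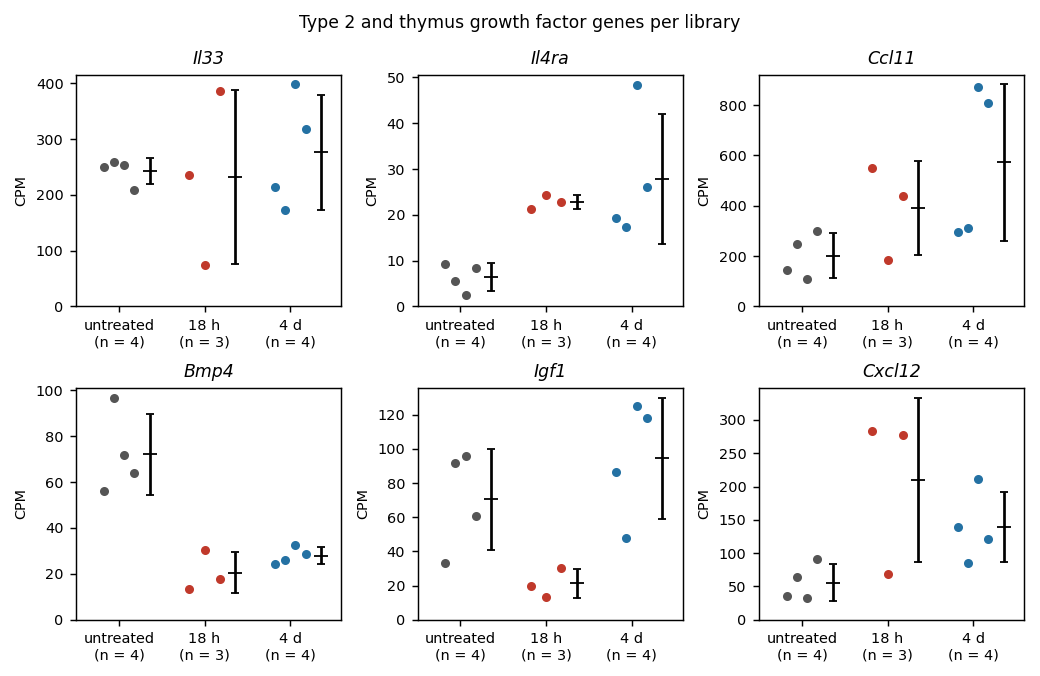
CPM of 3 type 2 genes and 3 growth or chemotactic factors, with a point per library in the untreated (n = 4), 18 h (n = 3) and 4 d (n = 4) groups, and a line with bars for the mean and SD of each group. Bmp4 averaged 72.2 CPM untreated, 20.5 CPM at 18 h and 28.0 CPM at 4 d.

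The fibroblast genes Pdgfra and Cd34, both used in the sort, stood at -0.68 ± 0.35 and -0.48 ± 0.24 at 18 h and did not pass. Ly6a, which is also induced by interferon, rose by 2.40 ± 0.29 and Pdgfrb, which pericytes also express, by 1.86 ± 0.38, while the 20 pan-fibroblast genes had a median of -0.48 (camera adjusted p = 0.123). The scavenger chemokine receptor Ackr3 rose by 1.33 ± 0.25 within 13 adventitial or capsular genes with a median of -0.20 (0.484). With the marker covariate Pdgfra passed at -1.68, the pan-fibroblast and adventitial lists were called downward (0.0432 and 0.0423), and Pdgfrb and Ackr3 lost their calls at 1.65 and 0.74. Among the named genes with the largest falls were Cpxm2 at -4.32 ± 0.71, Angptl1 at -4.02 ± 0.68, Pdgfrl at -3.52 ± 0.65, Ptprd at -3.47 ± 0.54 and Tmem132c at -3.33 ± 0.57.

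Metabolic, complement and lysosomal genes changed singly at 18 h. The glucose transporter Slc2a1 rose by 2.14 ± 0.45, Rdh10, which makes the precursor of retinoic acid, by 1.69 ± 0.30, and the scavenger receptor Stab1 by 3.51 ± 0.44. The complement gene Cfb rose from 703 ± 245 CPM (SD, n = 4) to 2813 ± 1029 CPM (SD, n = 3), and Colec12 fell by 1.38 ± 0.27 on the log2 scale. Slc2a1 and Colec12 lost their calls with the marker covariate, at 2.29 and -0.89. List medians were 0.28 for hypoxia and glycolysis (camera adjusted p = 0.0842), -0.12 for retinoic acid genes (0.950), 0.20 for complement (0.70), 0.15 for phagocytosis and lysosome (0.368), -0.26 for TGF-beta and myofibroblast genes (0.70), -0.25 for adipogenesis (0.70), -0.51 for cell cycle (0.102), -0.11 for cholesterol synthesis (0.813) and 0.20 for oxidative phosphorylation (0.102). The cell cycle list was called downward without 18 h replicate 1 (0.0306) or 4 d replicate 1 (0.0474). Fits of only the 2 groups gave both the cell cycle and the hypoxia and glycolysis list an adjusted p below the threshold (0.0274 and 0.04998).

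Camera called 4 further lists upward at 18 h, none of which was called with an estimated correlation. Medians were 0.45 for endoplasmic reticulum stress (adjusted p = 0.0383, and adjusted p = 0.652 with an estimated correlation), 0.49 for p53 response (0.0344, and adjusted p = 0.512 with an estimated correlation), 0.54 for immediate early genes (0.0251, and adjusted p = 0.704 with an estimated correlation) and 0.26 for ribosomal proteins (0.0385, and adjusted p = 0.757 with an estimated correlation). The stress call was lost without untreated replicates 3 or 4 (0.102 and 0.0583) or 18 h replicates 1 or 3 (0.0856 and 0.184), and the p53 call without untreated replicates 1 or 3 (0.0610 and 0.0717) or 18 h replicate 3 (0.0896). The immediate early call was lost without untreated replicates 3 or 4 (0.212 and 0.0514) or 18 h replicates 2 or 3 (0.0552 and 0.0963), and the ribosomal call without untreated replicates 1, 2 or 3 (0.0820, 0.0981 and 0.0717) or any 18 h replicate (0.0661, 0.0594 and 0.0843). A filter of 20 counts ended the calls of stress, p53 and ribosomal genes (0.117 each) and of immediate early genes (0.0635). Leaving out the 2 shallow libraries ended the immediate early call (0.0642), and upper-quartile scaling and the mesothelial covariate the ribosomal call (0.0778 and 0.0955). Over the alternatives at the preset correlation and without a replicate block, the highest adjusted p of the 4 lists were 0.219, 0.665, 0.341 and 0.947. All came with the marker covariate.

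Across all genes, 1262 of 10067 passed at 18 h, 790 higher and 472 lower, and 1059 of them changed at least 2-fold. The groups did not overlap for 2380 genes, 23.6% of those tested, where chance gives 5.71%. The authors' deposited table held 1639 genes at an adjusted p below 0.05, of which 1238 were also called here in the same direction. The count fell to 807 without untreated replicate 2, 715 without untreated replicate 3, 814 without untreated replicate 4 and 668 without 18 h replicate 1. With the marker covariate, chosen after seeing the data, 613 genes passed. Of the 1262 genes, 409 kept their call in the same direction with it, and 22 changed sign. Without the 2 shallow libraries, 18 h replicate 2 and 4 d replicate 4, 1123 genes passed.

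**Figure D4:**
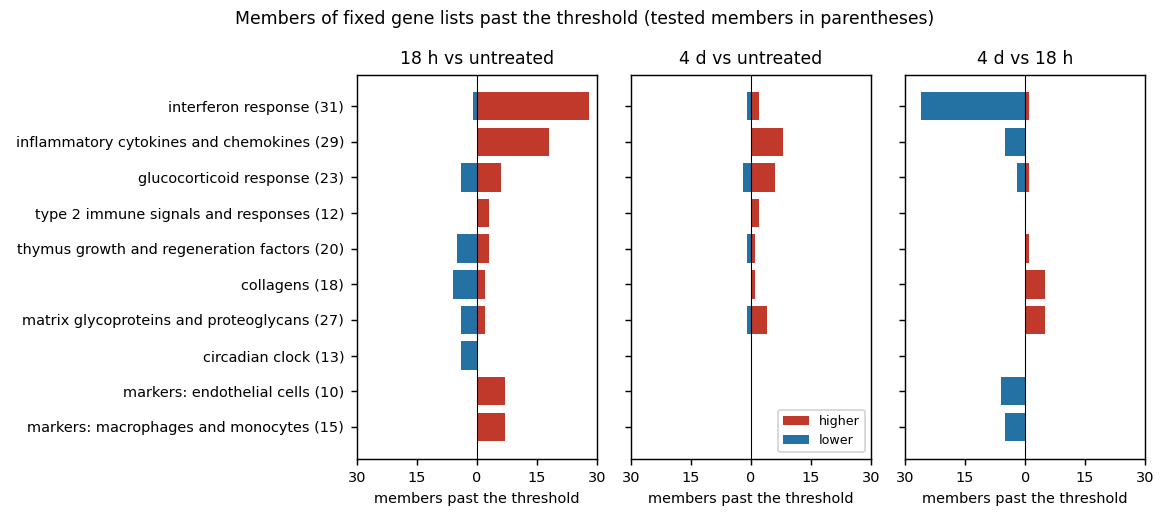
Number of members of 10 gene lists past the threshold in each comparison, higher to the right and lower to the left, with the number tested in parentheses. Interferon genes had 28 higher members at 18 h and 26 lower members between 18 h and 4 d.

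The second comparison asked what still differed from untreated fibroblasts at 4 d. The lists of matrix glycoproteins and of matrix remodelling genes stood above the other genes, although few members of either passed. Of 27 matrix glycoproteins and proteoglycans 4 rose and 1, Fmod, fell (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00725, and adjusted p = 0.512 with an estimated correlation), with the hyaluronan synthases Has2 and Has1 at 2.67 ± 0.43 and 1.92 ± 0.36 and Thbs1 at 2.35 ± 0.40. The lower count was 0 without untreated replicates 2, 3 or 4, 18 h replicate 1 or 4 d replicates 3 or 4, and 2 without 18 h replicate 2. Among other named genes, Ptx3, a pentraxin that binds hyaluronan matrix, rose from 146 ± 102 CPM to 1598 ± 688 CPM (SD, n = 4 each), a log2 difference of 3.45 ± 0.49 (adjusted p = 0.00393). Tnfaip6, which links hyaluronan to proteins and is in the inflammatory list, rose by 2.81 ± 0.40. Fgf23, a phosphate-regulating hormone gene (chromosome 6, 127072902 to 127081408), rose by 4.46 ± 0.57, Nptx2 by 4.41 ± 0.81 and the proteoglycan-cleaving Adamts4 by 3.19 ± 0.47. The size for Nptx2 is uncertain, since it was at 3.11 CPM in untreated replicate 1 and 0.357 to 0.560 CPM in the other untreated libraries. The remodelling list had 4 of 28 higher (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00167, and adjusted p = 0.512 with an estimated correlation), with Timp1 at 2.48 ± 0.32 and the crosslinking enzyme Lox at 1.55 ± 0.24. Without untreated replicates 2, 3 or 4 or 4 d replicates 1 or 3, 2 remodelling genes rose. At the preset correlation and without a replicate block the list's adjusted p ranged from 9.55e-05 to 0.0513, the latter with mesothelial markers as a covariate. Limma-voom ended the call of Nptx2, at 4.55.

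Inflammatory genes were still above untreated at 4 d as a list. Of 29 tested, 8 rose and 0 fell (17 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.1e-11, and adjusted p = 0.512 with an estimated correlation). Interferon genes had a median of -0.03 and a mean of 0.13 (camera adjusted p = 0.626), and Isg15, chosen after its value was seen, stood at -0.19 ± 0.21. The count of higher inflammatory genes was 1 without untreated replicate 2, 2 without untreated replicate 3, 3 without untreated replicate 4, 5 without 18 h replicate 1, 13 without 18 h replicate 2, 4 without 4 d replicate 1, 1 without 4 d replicate 3 and 4 without 4 d replicate 4.

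Receptors and growth factors differed singly at 4 d. Il4ra was at 27.8 ± 14.2 CPM (SD, n = 4), 2.13 ± 0.41 above untreated on the log2 scale (adjusted p = 0.0132), and Bmp4 at 28.0 ± 3.58 CPM (SD, n = 4), a difference of -1.37 ± 0.26 (adjusted p = 0.0132). Il33 stood at 0.18 ± 0.38 and the eosinophil chemokine Ccl11 at 1.51 ± 0.44, with neither past the threshold, and Ccl11 passed without 18 h replicate 2 (0.0410). Type 2 genes had 2 higher of 12 (5 adjusted over the list alone; camera adjusted p = 0.0146, and adjusted p = 0.512 with an estimated correlation), where 1 rose without untreated replicates 2, 3 or 4, 18 h replicate 1, or 4 d replicates 1, 3 or 4. That list call was lost with only the 2 groups compared (0.0692), without the 2 shallow libraries (0.0642) and with the mesothelial covariate (0.0618), in a range of 0.00449 to 0.0692. The thymus growth factors had a median of -0.30 (camera adjusted p = 0.497), Rdh10 was at 49.4 ± 9.93 CPM against 17.7 ± 2.67 CPM, and the adventitial genes Ackr3 and Creb5 and the receptor Stab1 rose by 1.27 ± 0.24, 1.61 ± 0.27 and 2.77 ± 0.43. The adventitial list, not called with all libraries, was called without untreated replicates 2 or 4 (camera adjusted p = 0.0333 and 0.0325) or 4 d replicate 1 (0.0192).

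Genes known to respond to glucocorticoids went both ways at 4 d as well, and 2 glucose metabolism genes rose. Glul, the glutamine synthetase gene, rose by 2.36 ± 0.39, and Ddit4 and Txnip, which limit mTOR signalling and glucose uptake, stood at -1.71 ± 0.27 and -2.02 ± 0.31. Hk2, a hexokinase gene, and Slc2a1 rose by 2.76 ± 0.51 and 2.28 ± 0.42, Eid3 rose by 3.39 ± 0.45, and Ecrg4 and Tmem204 stood at -2.20 ± 0.27 and -2.36 ± 0.39, all past the threshold. Hk2 and Slc2a1 were the 2 higher of 17 hypoxia and glycolysis genes (5 adjusted over the list alone), a list with a median of -0.05 and a mean of 0.54 (camera adjusted p = 0.270). Without 18 h replicate 2, 4 of its genes rose. Of 34 oxidative phosphorylation genes 0 passed (0.695), and the cholesterol synthesis list had a median of -0.06 (0.825). The cell cycle list, not called with all libraries, was called without 4 d replicate 1 (camera adjusted p = 0.00366). In the glucocorticoid list 6 of 23 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0383, and adjusted p = 0.512 with an estimated correlation). The call was lost without untreated replicates 1 or 4 or 4 d replicate 2 (0.0549, 0.0788 and 0.0950). It was also lost with a filter of 20 counts (0.109), with only the 2 groups compared (0.0889) and with the marker covariate (0.0724). At the preset correlation and without a replicate block the range was 0.0123 to 0.109. The higher count was 3 without untreated replicate 2 or 4 d replicates 3 or 4 and 1 without untreated replicate 4.

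Camera called 6 further lists upward at 4 d, none of them with an estimated correlation. Medians were 0.33 for ribosomal proteins (adjusted p = 3.9e-05, and adjusted p = 0.550 with an estimated correlation), 0.45 for endoplasmic reticulum stress (0.00457, and adjusted p = 0.550 with an estimated correlation), 0.28 for immediate early genes (0.0381, and adjusted p = 0.720 with an estimated correlation), 0.32 for p53 response (0.0381, and adjusted p = 0.512 with an estimated correlation), 0.32 for pan-fibroblast genes and 0.31 for phagocytosis (0.0383 and 0.0464, and adjusted p = 0.598 for each with an estimated correlation). The stress call was lost without 4 d replicate 1 (0.0598). The immediate early call was lost without untreated replicates 3 or 4 or 4 d replicate 4 (0.476, 0.0759 and 0.0676) and the p53 call without untreated replicates 1 or 3 or 4 d replicate 2 (0.0605, 0.110 and 0.0543). The pan-fibroblast call was lost without untreated replicates 1 or 3 or 4 d replicates 3 or 4 (0.121, 0.102, 0.203 and 0.0798), and the phagocytosis call without untreated replicates 1, 2 or 3, 18 h replicate 3 or 4 d replicate 3 (0.0527, 0.0716, 0.102, 0.0593 and 0.172). A filter of 20 counts and fits of only the 2 groups each ended the immediate early, p53, pan-fibroblast and phagocytosis calls (0.210, 0.116, 0.0847 and 0.251 with the filter, 0.0677 each with the 2 groups). The marker covariate ended those of immediate early, pan-fibroblast and phagocytosis genes (0.0723, 0.0733 and 0.0772). The mesothelial covariate ended those of p53, pan-fibroblast and phagocytosis genes (0.0508, 0.551 and 0.170). Leaving out the 2 shallow libraries ended the immediate early and pan-fibroblast calls (0.0708 and 0.0716) and upper-quartile scaling the phagocytosis call (0.0528). The highest adjusted p over the alternatives were taken at the preset correlation and without a replicate block. They were 0.00587 for ribosomal proteins, 0.0598 for stress, 0.476 for immediate early genes, 0.116 for p53, 0.551 for pan-fibroblast genes and 0.251 for phagocytosis. The mesothelial genes Msln, Upk3b, Lrrn4 and Krt19 together were at 3499, 3462, 310 and 1090 CPM in 4 d replicates 1 to 4, against 2331 to 3807 CPM in untreated libraries. No marker list of other cell types was called by camera at 4 d. The thymocyte list was called with the mesothelial covariate (0.00108), with no filter (0.0117) and without the 2 shallow libraries (0.0306). It was also called without untreated replicate 1 (0.0317) or 4 d replicate 3 (0.0332). The list of mesothelium, Schwann and erythroid cells was called without 4 d replicates 1 or 2 (0.0245 and 0.0226).

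At 4 d 333 of 10067 genes passed, 250 higher and 83 lower, and 313 of them changed at least 2-fold. Groups did not overlap for 1472 genes, 14.6% of those tested, where chance gives 2.86%. The authors' deposited table held 626 genes at an adjusted p below 0.05, of which 332 were also called here in the same direction. The count was 152 without untreated replicate 2, 115 without untreated replicate 3, 135 without untreated replicate 4, 617 without 18 h replicate 2, and 217, 221, 129 and 205 without 4 d replicates 1, 2, 3 and 4. With the endothelial, macrophage and pericyte covariate it was 501, with the mesothelial covariate 168, and without the 2 shallow libraries 378.

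The third comparison tested directly how 4 d differed from 18 h. Interferon genes fell together, and the inflammatory list was lower. Isg15 stood at -3.96 ± 0.25, and Saa3, Lcn2 and Csf3, named for the size of their change or as leading list members, at -6.10 ± 0.34 (adjusted p = 2.8e-07), -5.41 ± 0.42 and -4.34 ± 0.51. Of 31 interferon genes 26 fell and 1 rose (29 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.4e-24, and adjusted p = 0.156 with an estimated correlation), including Zbp1 at -3.37 ± 0.23, Usp18 at -3.04 ± 0.24 and Ifit3 at -4.79 ± 0.30. Inflammatory genes had 5 lower of 29 (9 adjusted over the list alone; camera adjusted p = 0.00125, and adjusted p = 0.584 with an estimated correlation), 8 of the 30 then tested fell without untreated replicate 1, and the marker covariate ended the list call (0.407, in a range of 7.6e-06 to 0.407). The antigen presentation list had a median of -1.36 (camera adjusted p = 0.0146, and adjusted p = 0.608 with an estimated correlation). That call was lost without 18 h replicate 3 (0.107) or 4 d replicate 1 (0.0664) and with the marker covariate, which turned its direction (0.947, in a range of 6.9e-05 to 0.947).

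Collagens and matrix glycoproteins stood above the other genes as lists between 18 h and 4 d. Mfap4 was 2.01 ± 0.31 and Eln 1.62 ± 0.24 higher, the gelatinase gene Mmp2 1.95 ± 0.34, Dpt 1.75 ± 0.34 and Fbln2 1.39 ± 0.24, and Mmp3 fell by 3.66 ± 0.57 on the log2 scale. Collagens had 5 of 18 higher (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00420, and adjusted p = 0.519 with an estimated correlation) and matrix glycoproteins 5 of 27 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00125, and adjusted p = 0.512 with an estimated correlation). Most members of the other fibroblast and matrix lists did not pass. Of 20 pan-fibroblast genes 2 rose and 2, Ly6a and Pdgfrb, fell (12 and 2 adjusted over the list alone). Of 13 adventitial genes 0 passed (3 higher adjusted over the list alone). Of 28 remodelling genes 5 rose and 2, Mmp3 and Timp1, fell (10 and 2 adjusted over the list alone). Their medians were 0.89, 0.69 and 0.32 (camera adjusted p = 0.00284, 0.0131 and 0.0383, and adjusted p = 0.512, 0.550 and 0.663 with an estimated correlation). The remodelling call was lost without untreated replicate 3 (0.0541), 18 h replicates 1 or 3 (0.0987 and 0.146) or 4 d replicate 3 (0.169), with the mesothelial covariate (0.145) and with the marker covariate (0.0616), in a range of 0.0117 to 0.169. Without 18 h replicate 1 or 4 d replicate 3, 1 remodelling gene rose. The count was 2 without 4 d replicate 4 and 3 without untreated replicates 2, 3 or 4, 18 h replicate 3 or 4 d replicate 2. Without 18 h replicate 3, 4 pan-fibroblast and 4 adventitial genes rose, and 2 adventitial genes without untreated replicate 1. The lower count was 1 for pan-fibroblast genes without untreated replicates 2 or 4, 18 h replicates 1 or 2 or 4 d replicates 1, 2 or 4, and for remodelling genes without 18 h replicate 1 or 4 d replicate 1. The collagen count was 2 without 18 h replicate 1 or 4 d replicate 4, 1 without 18 h replicate 2 or 4 d replicate 3 and 3 without 4 d replicate 1, and the glycoprotein count 2 without 18 h replicate 1 and 3 without 4 d replicates 1 or 3. Fbln2 and Mmp3 lost their calls with the marker covariate, at 1.36 and -1.03.

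Other genes that had been low at 18 h were higher at 4 d. Angptl1 rose by 3.77 ± 0.67, Ptprd by 3.16 ± 0.55, Peg3, an imprinted gene, by 2.90 ± 0.53 and the pyruvate dehydrogenase kinase Pdk4 by 2.29 ± 0.44. Igf1 rose by 2.09 ± 0.43 to 94.4 ± 35.4 CPM (SD, n = 4), a call lost without 18 h replicate 1 (0.0673) or without the 2 shallow libraries, at 1.78. The 13 clock genes had a median of 1.05 (camera adjusted p = 0.00457, and adjusted p = 0.422 with an estimated correlation), which the marker covariate ended (0.43, in a range of 5.4e-04 to 0.43). Time of day is not separated from time after dexamethasone for the clock genes here either. Ddit4 fell by 3.23 ± 0.29 on the log2 scale. Ptprd and Pdk4 lost their calls with the marker covariate, at 3.00 and 2.55.

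Markers of endothelial cells, macrophages, pericytes, thymocytes and dendritic or B cells were lower as lists at 4 d than at 18 h. Endothelial markers summed to 1075 ± 511 CPM (SD, n = 4) at 4 d, each library below each 18 h library (exact two-sided permutation p = 0.0571, the smallest possible; adjusted p = 0.140). The sums of macrophage, pericyte, thymocyte, dendritic and B cell, and granulocyte and innate lymphoid markers were separated in the same way, with the same p. The dendritic and B cell sum at 18 h was nearly all Bst2, which is also in the interferon list, so it says little about those cells. Of 10 endothelial markers 6 fell (7 adjusted over the list alone; camera adjusted p = 0.00300, and adjusted p = 0.512 with an estimated correlation), of 15 macrophage markers 5 (9 adjusted over the list alone; 1.2e-04, and adjusted p = 0.512 with an estimated correlation), and of 13 pericyte markers 4 (5 adjusted over the list alone; 0.0131, and adjusted p = 0.584 with an estimated correlation), among them Mcam at -3.84 ± 0.68 and Tagln at -2.98 ± 0.49. Thymocyte and dendritic or B cell markers had medians of -1.97 and -1.49 (camera adjusted p = 0.00300 and 0.0127, and adjusted p = 0.512 for each with an estimated correlation). Only 2 of 6 tested thymocyte markers and 1 of 4 tested dendritic or B cell markers fell. The remaining marker lists were not called, at 0.0940 for tuft cells, 0.685 for thymic epithelium and 0.70 each for the granulocyte and innate lymphoid markers and for mesothelium, Schwann and erythroid cells. The directional fry test called the tuft list downward (adjusted p = 0.0296), and camera called it without 18 h replicate 2 (0.0123), without the 2 shallow libraries (0.0169), with no filter (0.0255), with limma-voom (0.0424) and with the mesothelial covariate (0.0415), and the granulocyte and innate lymphoid list with no filter (0.0270). Without 18 h replicate 1, 1 macrophage and 2 pericyte markers fell, and the pericyte call was lost (0.123). Of the same 10 endothelial markers 0 fell without 18 h replicate 1, 2 without 4 d replicate 4, 3 without 4 d replicate 1 and 6 without 18 h replicate 2, when 17 passed the filter and 13 fell. Macrophage markers that fell numbered 8 without 18 h replicate 2, 2 without 18 h replicate 3, 1 without 4 d replicate 1 and 3 without 4 d replicate 2. The thymocyte call was lost without 18 h replicate 3 (0.0677) and with the marker covariate (0.916, in a range of 3.85e-05 to 0.916). That covariate also ended the dendritic and B cell call (0.269, in a range of 2.9e-05 to 0.269). The endothelial call was lost with a filter of 20 counts (0.0847). The endothelial and pericyte ranges, 1.15e-14 to 0.946 and 5.4e-04 to 0.899, end at the covariate made of these same markers, which removes their change by construction.

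Between 18 h and 4 d 555 genes passed, 171 higher and 384 lower, and 497 of them changed at least 2-fold. Groups did not overlap for 2020 genes, 20.1% of those tested, where chance gives 5.71%. The authors' deposited table held 874 genes at an adjusted p below 0.05, of which 549 were also called here in the same direction. The count was 241 without 18 h replicate 1 and 344 without 4 d replicate 1, and 475 without the 2 shallow libraries.

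The last comparison counted genes called at both times against untreated. There were 146 called higher at both times and 31 called lower. Of the 790 genes higher at 18 h 304 (38.5%) fell between 18 h and 4 d, and of the 472 lower genes 110 (23.3%) rose. Both comparisons use the same 18 h libraries, so genes chosen for their 18 h values are favoured to move back. No share for unchanged genes was computed. Independent lists of the sizes called at 18 h and 4 d would share 19.6 higher and 3.89 lower genes. The 50 simulated pairs of unchanged groups against the same untreated libraries shared at most 0. Those pairs called on average 0.1 genes at 18 h and 0.08 at 4 d, too few to show what shared libraries add. When the untreated libraries were divided so that each time had its own 2, the 6 divisions gave 0 to 34 higher and 0 to 9 lower shared genes. Independent lists would share at most 3.63 and 0.367. Divisions that gave untreated replicate 3 to 18 h called 0 genes higher and at most 1 lower at 4 d, so they could share almost none. The others shared 34, 34 and 17 higher genes, against 3.63, 2.76 and 1.47 for independent lists. In these an excess was seen without shared untreated libraries. Part of the excess among the 146 and 31 genes may still come from the shared untreated libraries. The 177 shared genes became 268 without untreated replicate 1, 78 without untreated replicate 2, 63 without untreated replicate 3, 79 without untreated replicate 4 and 89 without 4 d replicate 3. The marker covariate gave 109 and the mesothelial covariate 111.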

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

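The tests of endothelial cells in the sort, of a lower share of fibroblasts and of mesothelial cells and depth were chosen after the results they bear on had been seen, as were the fits with marker covariates and without the 2 shallow libraries. In each comparison the real split called the most genes of 35 splits of the same libraries. It called 1262 at 18 h, 333 at 4 d and 555 between the times, and the highest other splits gave 668, 0 and 32. This speaks against a chance division, but 1 of 35 is the smallest share possible, so chance is not excluded. The split with 668 moved only untreated replicate 1 to the side of the 18 h libraries, so it kept most of the real division. On log2 CPM, untreated replicate 1 correlated with the other untreated libraries at 0.918 to 0.930. Those correlated with each other at 0.953 to 0.959. The splits also treat the libraries as separate samples, which the labels do not state.

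Interferon-response genes rose at 18 h with a median log2 difference of 2.21. Leaving out the 2 shallow libraries argues against depth as the whole cause, since 92.9% of the higher members (26 of 28) were still higher. Endothelial, macrophage and pericyte cells in the sort could account for part of it. With their markers as a covariate the median was 1.79, with a median SE of 0.49 and 16 members higher, which leaves that explanation open. A response to dexamethasone or to the injection is the biological candidate and was not tested apart from it.

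Endothelial markers rose at 18 h with a median of 2.85. A lower share of fibroblasts would raise other cell types alike. The mesothelial markers stood at -0.43, against 2.85 for the endothelial ones. The SE of that difference, built from median SEs of single genes, was 0.87. All the other marker lists had medians above 0, at 1.92 for dendritic and B cells, 1.20 for macrophages and 1.18 for thymocytes. Medians were 1.08 for granulocytes and innate lymphoid cells, 0.63 for tuft cells, 0.46 for pericytes and 0.12 for thymic epithelium. This argues against an equal rise of all cell types, but not against a lower share of fibroblasts with unequal rises. Scaling is argued against as well, as the lowest median under other scalings was 2.75. Endothelial cells in the sort may be the source: the 10 members' mean correlation within groups was 0.317, at the 97.0th percentile of random sets of called genes, although CD31, the product of Pecam1, was to exclude them. A change in their number in the tissue stays open and was not tested.

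Mesothelial markers were low in 4 d replicates 3 and 4. Depth is argued against for replicate 3, which held 3.36 M counts, the most of any library. Replicate 4 held 0.916 M, the fewest of any library, so its total does not argue against depth there. Fewer mesothelial cells in those libraries may be the source but stay a hypothesis. In the 7 libraries outside the 4 d group the markers' mean correlation within groups was 0.507, at the 98.4th percentile of random sets, although Wt1 correlated with the others at only -0.30 to 0.35. This shows markers that moved together elsewhere, not why they were low here. No biological explanation was tested.

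Single libraries stood apart from the other 3 of their group in 19 of 338 groups tested, where chance gives about 1 in 20, or 16.9. The ratio of the gap to the range follows each. In 4 d replicate 3 these were Adamts4 (0.854), Ccl3 (0.909), Csf3 (0.846), Fcer1g (0.882), Slc2a1 (0.860), Timp1 (0.832) and Tnfrsf19 (0.902), and in 4 d replicate 4 Lpl (0.888). In untreated replicate 1 they were Calr (0.831), Colec12 (0.937), Epcam (0.926), Nptx2 (0.926) and the tuft cell marker sum (0.842), and in untreated replicate 2 Angptl1 (0.915). In untreated replicate 3 they were Adamts1 (0.918) and Cxcl14 (0.929), and in untreated replicate 4 Fn1 (0.948), Gpihbp1 (a ratio of 1) and Mcam (0.916). Epcam was at 10.4 CPM in untreated replicate 1 and 0.378 to 1.12 CPM in the others.

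The change from untreated differed between 4 d and 18 h for 555 genes by the direct test. In 5 of them the changes from untreated passed at both times in opposite directions, higher at 18 h and lower at 4 d. The differences of 4 d from 18 h were -3.29 for Apol9a, -2.90 for Apol9b, -3.23 for Ddit4, -2.70 for Ier5l and -4.79 for Ifit3. Apol9a, Apol9b and Ier5l were chosen after their values were seen, and the first pair may share reads as near copies. The call of Ifit3 at 4 d was lost without untreated replicates 3 or 4 (adjusted p = 0.0651 and 0.0873) or 4 d replicates 1 or 4 (0.0663 and 0.0692).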

How the results depend on the processing

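The fits with marker covariates and without the 2 shallow libraries were chosen after seeing the data. Of the named gene values under the alternatives, 10707 kept their side of the threshold, and 871 lost and 219 gained the call. A further 3, called before any alternative was applied, turned direction. Of the list tests 2222, 142, 48 and 2 did so. Values that turned direction without such a first call are counted as kept or gained. Leaving out 1 library moved the genes passing at 18 h between 668 and 1530, at 4 d between 115 and 617 and between the times from 241 to 807, the shared genes from 63 to 268 and the list calls from 28 to 40 (37 with all libraries). The filter of 20 counts left 21 list calls, with fewer genes tested, and the estimated correlation 0, where 37 lists were called by camera with the preset value. DESeq2 called 651 genes at 4 d and 874 between the times, with 320 shared, and fits of only the 2 groups 538 and 355. The marker covariate gave 613 genes at 18 h, 501 at 4 d, 109 shared and 17 list calls, and the mesothelial covariate 168 at 4 d and 111 shared. The marker covariate also turned Ptprc (-0.055) and Cd83 (-0.80) at 18 h and Egfl7 (0.31) between the times, and there the antigen presentation and pericyte list tests (adjusted p = 0.947 and 0.899). Egfl7 and the pericyte markers are part of that covariate, which removes their change by construction. For the others the cause was not tested, except where fewer genes or samples entered. Upper-quartile scaling shifted the median of all genes at 18 h by -0.103 on the log2 scale and gave 681 higher and 588 lower, 53.7% higher against 62.6%.

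With the replicate number as a block, the title numbers gave 648, 60 and 305 genes at 18 h, at 4 d and between the times and 33 shared, and the description numbers 418, 91, 364 and 40. No clear pairing by these numbers was seen. By title, 2 of 10 pairs had deviations correlated over 0.1 (-0.34 to 0.19), and by description 1 of 8 (-0.14 to 0.36). Of 11 libraries 0 correlated best with their own title number, which was not checked for description numbers. So few pairs cannot exclude that the numbers mark a shared day or batch. List tests were not run for DESeq2 or the fold limit, and mitochondrially encoded genes could not be left out, so that alternative removed the 95 ribosomal protein genes. Depth limits the 2 shallow libraries most, where a count of 0 allows 3.65 and 3.74 CPM.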

Other observations

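The test of imprinted genes was set before its result was seen but after the falls of H19, Peg3 and Cdkn1c had been noticed, and the genes below were chosen after their values were seen. H19, a maternally expressed long noncoding RNA that is high in fetal tissue, fell by 2.97 ± 0.62 on the log2 scale at 18 h, and the growth inhibitors Cdkn1c and Grb10 stood at -1.87 and -1.02, both past the threshold in edgeR's test. The imprinted genes Ndn and Sgce passed as well, at -1.18 and -1.03. That an imprinted growth network falls together was a hypothesis. In the list of imprinted genes without those 3, 4 of 15 tested members fell and 0 rose, with a median of -0.28, and camera gave p = 0.110 (p = 0.361 with an estimated correlation), so the list as a whole did not pass.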
